A study of Gallus gallus with 25 samples.

How the data were processed

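The files used were a table of a comparison between Wnt knockdown and control neural folds and a list of chromatin contacts for each of 6 H3K27ac HiChIP libraries. Per the labels' protocols, embryos were injected bilaterally with morpholinos against Wnt1 and Wnt4 on a side and control morpholino on the other, single neural folds were dissected in pairs, and poly(A) RNA libraries were made with a directional kit. Per the submitters' processing notes, the RNA reads were handled with cutadapt, HISAT2, featureCounts and DESeq2 on build galGal5. The authors deposited for each gene a mean normalised count over all libraries, a signal that is counts divided by size factors, together with a log2 fold change and its standard error, a Wald score and a p-value with its adjusted p-value. Versions, the strand setting of the counting, whether the test used pairs, and which group is the numerator were not given in the sources used here. No values per library were used for RNA, so no new test between libraries was made, and genes were called at the deposited adjusted p under 0.05. That normalisation assumes that most genes do not change. Reads of near-identical or overlapping genes may have been split between them by the counting.

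Per the labels' protocols, HiChIP libraries were made from crosslinked cells of dissected neural folds and of whole embryos prepared in parallel, digested with MboI, pulled down with an antibody to H3K27ac, tagmented, amplified and read from both ends. Per the submitters' processing notes, HiC-Pro and MACS2 were used on build galGal5; the tool that listed the loops was not given in the sources used here. The authors deposited, per library, the count of PETs for each pair of anchors, with no header. Anchors differ between the files, so a contact can be missing from a library because its anchor was not called there, and PETs outside a library's anchors were not counted. Coordinates are those of the files, written from 1.

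Samples were grouped from their titles. Nothing in the labels says that the replicates are separate days or clutches, so p-values measure the spread between these libraries, which may be technical. Depth ranged from 26970022 to 43859081 PETs per HiChIP library; intervals and SDs cover these libraries only. No pair of libraries agreed within sampling noise: over 100 kb windows, chi-square per degree of freedom lay between 45.5 and 144 within groups.

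Anchors that overlapped across the 6 files were merged, and PETs were summed per pair of merged anchors. PETs between anchors that merged into 1 region, 5.50% to 6.48% of a library, were left out of the loops. Loops with at least 5 PETs in at least 3 libraries were tested (1318376 of 8317607 pairs, 80.5% of PETs, with a median of 10 PETs per library) with edgeR 4.0.16, using its quasi-likelihood test, TMM scaling on the tested loops, a trended dispersion and Benjamini-Hochberg adjustment at 0.05. Anchor totals, in which each PET counts at both of its anchors, were tested in the same way after the filter of edgeR. The share of PETs whose anchor midpoints lie over 100 kb apart was compared with a two-sided exact permutation test. Designs, gene lists and most alternatives were set before the data were examined. After it had been seen that anchors differed between libraries, loops between anchors covered over at least 80% in every library, totals per 100 kb window, shares per chromosome and pairs of 10 kb bins were added. The planned test of contacts per gene was not run, since no annotation of the build was used here. Alternatives were RLE scaling, DESeq2 1.42.0, a replicate block, other PET minimums (2 and 10), PETs scaled within 8 distance classes, windows of 50 and 250 kb, and leaving out each library in turn.

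Gene lists, 24 in all, were tested with cameraPR of limma 3.58.1 on the Wald score, with a preset correlation of 0.01 between genes and adjustment over the 23 lists with at least 3 measured genes. The 27 HOX genes of the other list were not analysed here. List medians were also placed among 10000 random lists matched on mean count in 20 bins. Alternatives were the log2 fold change in place of the score, a correlation of 0.05, and genes with a mean count of at least 50. A correlation estimated from libraries could not be had without values per library.

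Genes named in the text follow a rule set before the data were examined: the morpholino targets, the 10 largest rises and falls among called genes with a mean count of at least 50, and up to 4 members per list with the smallest adjusted p. At most 2 unnamed genes per direction are printed. Loops and anchors named are among the 5 largest changes per direction among calls whose libraries do not overlap between groups, and windows, added later, were named in the same way, with called windows next to them. Names came from the deposited table, without a symbol for 2130 of 13442 genes; a RefSeq gene table of another assembly, GRCg7b, served only to look up which genes neighbour each other.

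The count tests were run on simulated data with 100 changed items for each of 2 fold sizes. A 4-fold change was recovered for 36.0% of the changed loops among 131838 simulated loops, 71.0% with 87420 covered loops, 68.0% with 75633 anchors and 100% with 10079 windows. A 2-fold change was recovered for 0, 27.0%, 41.0% and 99.0%. The list test recovered a list shifted by -1.5 in the Wald score in 99.0% of 100 shuffles of 11287 genes. Shuffling removes correlation between genes, and smaller shifts were not simulated. Computations used R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, pyarrow 21.0.0, the R package data.table (1.17.8) and matplotlib 3.10.9.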

Results

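The series profiled the chick embryo at the stage when the neural crest is specified, which the series design gives as HH9 on the Hamburger and Hamilton scale. The neural crest is a migratory cell population that forms at the neural folds, the raised edges of the neural plate, and gives rise to pigment cells, peripheral neurons and glia, and much of the facial skeleton. The labels list 25 samples. The comparisons below use an RNA comparison of 3 knockdown with 3 control libraries and H3K27ac HiChIP of 3 neural fold and 3 whole embryo libraries, while the CUT&RUN and ATAC libraries were not analysed here. HiChIP joins DNA ends that lie close together in the nucleus and then pulls down fragments carrying a chosen mark, here acetylated lysine 27 of histone H3, found at active enhancers and promoters. Each paired-end tag (PET) records a contact between a pair of regions, called anchors.

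The RNA comparison asked which genes respond when the ligands Wnt1 and Wnt4 are blocked in the neural folds with morpholinos, antisense oligonucleotides that interfere with translation or splicing. FOXD3 and SNAI2, transcription factors that specify the crest and drive its delamination, fell in the authors' deposited table, with log2 fold changes of -1.63 (adjusted p = 3.6e-11) and -1.40 (adjusted p = 7.3e-07). DRAXIN, a secreted Wnt antagonist of the cranial crest, fell by 0.91 and MSX1, a border and crest transcription factor, fell by 0.63 on the log2 scale in the authors' deposited table. EPCAM, an epithelial adhesion molecule, rose with a log2 fold change of 1.74 (adjusted p = 4.1e-12) in the authors' deposited table. Of 12658 genes with an adjusted p in the authors' deposited table, 254 changed, 83 of them rising and 171 falling.

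The morpholino target WNT4 had a log2 fold change of -0.77 with a standard error of 0.86 and an adjusted p of 0.850 in the authors' deposited table, so no change of its transcript passed the test. WNT1 was not analysed here. A morpholino need not alter the level of its target's transcript, so these values do not check the knockdown.

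Beyond the crest genes, the largest falls among genes with a mean normalised count of at least 50 in the authors' deposited table were those of EN1, a midbrain and hindbrain transcription factor (-1.86), FOXD3, PCSK1, a prohormone convertase (-1.63), LRRN2 (-1.60), BMPER, a modulator of BMP signalling (-1.48), CNTN3, a contactin (-1.44), and TFAP2E (-1.41), with SNAI2 and 2 genes known only by identifier, ENSGALG00000042467 (-1.70) and ENSGALG00000034843 (-1.65). The largest rises at a mean count of at least 50 in the authors' deposited table included the sarcomeric actins ACTA1 (log2 fold change 2.22) and ACTC1 (2.08), the muscle actin nucleator LMOD1 (2.16) and the acyltransferase MOGAT2 (1.81). Unnamed genes with the highest log2 fold changes at that mean count in the authors' deposited table were ENSGALG00000030680 (3.12) and ENSGALG00000044971 (2.56). In all, 48 of the 254 changed genes carried no symbol in the authors' deposited table.

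Crest specifiers moved down as a group. Of 27 measured specifiers, 5 fell and none rose in the authors' deposited table, and adjusted over the list alone 9 fell and 1 rose. Their median log2 fold change was -0.39 in the authors' deposited table, at percentile 0 of 10000 random lists matched on mean count. The list test gave an adjusted p of 2.6e-07. Genes of crest delamination and migration also moved down, with 3 of 31 falling in the authors' deposited table, 7 falling when adjusted over the list alone, a median of -0.31 and an adjusted p of 7.9e-06. The 3 were CDH6, a cadherin of premigratory crest (log2 fold change -0.93), ITGA4, an integrin subunit (-0.87), and NRP2, a semaphorin receptor (-0.77), in the authors' deposited table.

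Placode and epidermis genes, markers of the neighbouring surface ectoderm, moved up, with a median log2 fold change of 0.32 over 24 measured genes and an adjusted p of 2.7e-05 in the test on the authors' deposited table. Of these genes 2 rose, EPCAM among them, and 1, TFAP2E, fell in the authors' deposited table, with the same counts when adjusted over the list alone. Of 8 lists of cell types other than crest, placode and epidermis included, 7 had a median above 0.1. The highest was 0.55 for endoderm. Genes with a mean count under 50 had a median of 0.17 in the authors' deposited table, which can lift lists of such genes. Among random lists matched on mean count, medians lay at percentile 100 for placode and epidermis and 99.5 for notochord and floor plate. Endoderm lay at 99.2, heart at 96.5 and blood and endothelium at 95.55. Forebrain lay at 90.1, paraxial mesoderm at 88.3 and neural plate and tube at 56.9. Among those 8 only the placode and epidermis list was called. Genes of the p53 response, a known side effect of morpholinos, moved up with an adjusted p of 0.0117, and its alternatives ranged from 0.0116 to 0.0811, the last of these with a correlation of 0.05 between genes assumed. TNFRSF10B, a death receptor (log2 fold change 1.26), EDA2R, another receptor of that family (1.12), and CDKN1A, a cell cycle inhibitor (1.64), rose in the authors' deposited table, 3 of 18 measured members, and 4 rose and 1 fell when adjusted over the list alone.

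Feedback targets of canonical Wnt signalling did not pass the list test. Their median lay at percentile 0.01 of random lists matched on mean count, a placing that ignores correlation between genes. None of 17 measured targets changed at an adjusted p under 0.05 in the authors' DESeq2 test, over all genes or over the list alone, while 1450 genes of the authors' deposited table passed an unadjusted 0.05, where 672 would by chance. AXIN2, the classical negative feedback gene, had a log2 fold change of -0.60 with an adjusted p of 0.463, and NKD1 -0.95 with 0.507, in the authors' deposited table. The median of the list was -0.30, and its adjusted p of 0.143 ranged from 0.0116, with log2 fold changes in place of the test statistic, to 0.292 over its alternatives. Neural plate and tube genes had a median of 0.01 over 24 genes (adjusted p = 0.931), and the direction of their test turned from up to down among genes with a mean count of at least 50.

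The authors' deposited table does not name its numerator, so each direction above rests on reading it as knockdown over control. The table gives no values per library, so the pairing of folds from the same embryos and the weight of single libraries were not tested here, and the labels give no depth for these libraries.

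**Figure D1:**
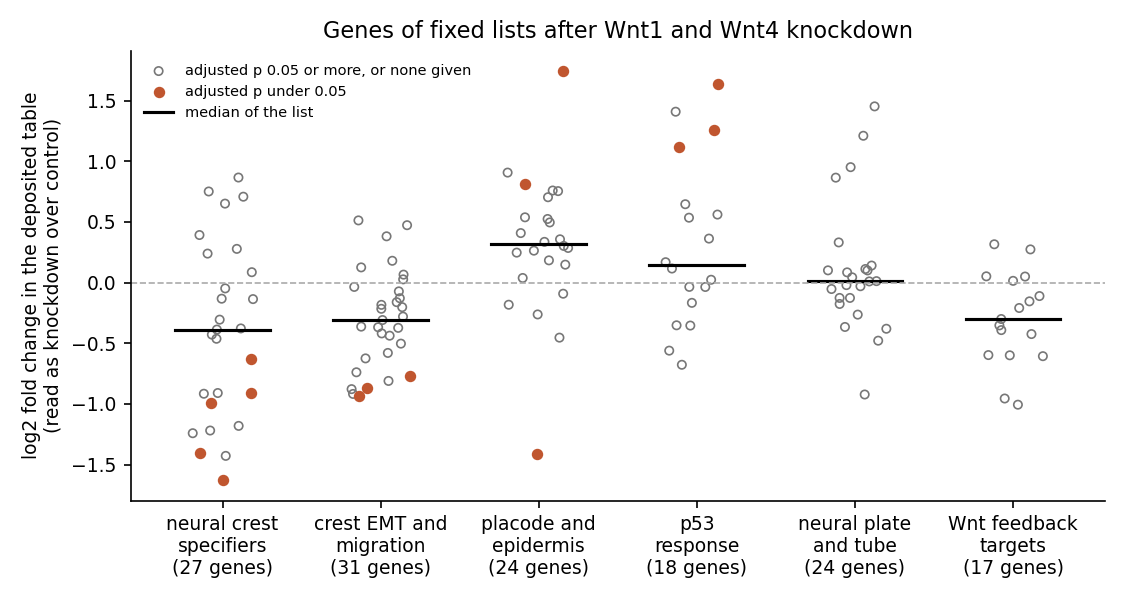
Each point is a gene of a list fixed before the data were examined, with its log2 fold change from the authors' deposited table on the vertical axis and the list on the horizontal axis; filled points have an adjusted p under 0.05 and bars are list medians. Medians of the crest lists lie at -0.39 and -0.31 and that of placode and epidermis genes at 0.32.

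HiChIP contacts of dissected neural folds were compared with those of whole embryos, which asks where acetylated chromatin makes contacts that differ between the tissue that holds the crest and the embryo at large. PET counts, written here as contacts, were lower in neural folds at a stretch of chromosome 27 and a stretch of chromosome 2. Such counts depend on the acetylation pulled down as well as on contact frequency, and these were not told apart here. The window from 3800001 to 3900000 on chromosome 27 (build galGal5) held 185 ± 3.85 CPM (PETs scaled to library size) in whole embryos (SD, n = 3) and 55.7, 42.2 and 52.1 CPM in the 3 neural fold libraries, a log2 fold change of -1.89 with an adjusted p of 5.0e-07 from edgeR. The window from 32600001 to 32700000 on chromosome 2 held 208 ± 13.4 and 87.8 ± 3.69 CPM (SD, n = 3 each), a log2 fold change of -1.25 with an adjusted p of 1.1e-04 from edgeR. Contacts were higher in neural folds on chromosome 3 from 99700001 to 99800000 (143 ± 14.6 against 258 ± 42.3 CPM, log2 fold change 0.85), on chromosome 7 from 3000001 to 3100000 (0.83), on chromosome 9 from 7600001 to 7700000 (0.82), on chromosome 21 from 800001 to 900000 (0.79) and on chromosome 8 from 27800001 to 27900000 (0.67), with adjusted p from 0.0261 to 0.0426 from edgeR. Each of these 5 kept its call in 6 of 10 alternatives. Over all windows of chromosomes 3, 7, 9, 21 and 8, median log2 fold changes were -0.03, 0.03, 0.09, 0.16 and 0.07. Without neural fold replicate 2 or whole embryo replicate 3 edgeR called 0 windows higher and 2 lower. No annotation of that build was used here, so genes at these regions are not named.

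The 6 libraries held from 26970022 to 43859081 PETs, between pairs of anchors 5 kb to 2 Mb apart. Anchors had been called in each library on its own: of 447538 distinct anchors, 3883 were shared by all 6 libraries and 301004 occurred in 1. Overlapping anchors were therefore merged into 81320, of which 15729 were covered over at least 80% of their length in every library. The protocol gives HH9 and the same preparation for both tissues. The characteristics of the whole embryo replicates instead carry stages 10, 11 and 12 and those of the neural fold replicates 13, 14 and 15. These tags rise in the order in which the samples are listed, so they may not record stages. If they do, stage and tissue could not be separated. Each neural fold replicate pooled 120 embryos and each whole embryo replicate 20. Correlations of window signal were 0.919 to 0.953 within a group and 0.901 to 0.940 between groups, across windows, which are not independent. Neural fold replicate 3 correlated at 0.919 with neural fold replicate 1 and 0.945 with neural fold replicate 2. With whole embryo replicates 1, 2 and 3 it correlated at 0.938, 0.929 and 0.940, so the libraries did not separate cleanly by tissue.

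Over 10079 windows of 100 kb, a test added after the data were examined, 35 were higher and 22 lower in neural folds, and all 57 had libraries that did not overlap between groups, as 22.4% of tested windows did where chance gives 10%. Neighbouring windows of the regions named above were also lower, from 3900001 to 4000000 on chromosome 27 (log2 fold change -0.77) and from 32500001 to 32600000 on chromosome 2 (-0.67). A window on chromosome 33 from 1000001 to 1100000 (-1.27) and another on chromosome Z from 81100001 to 81200000 (-0.93) were lower, and a window on chromosome W from 2100001 to 2200000 held 1.23 ± 1.13 CPM in whole embryos and was listed at 0 in the 3 neural fold libraries, whose anchors covered 0 kb of it. These 3 windows kept their calls in 6, 7 and 4 of 10 alternatives. The chromosome 33 window was covered over 66.6 ± 6.54 kb in whole embryos and 40.3 ± 14.9 kb in neural folds, with 0.63 ± 0.0722 and 0.442 ± 0.0376 CPM per covered kilobase (SD, n = 3 each), a log2 ratio of -0.51. The chromosome Z window was covered over 62.2 ± 6.25 and 49.4 ± 1.42 kb, with 1.09 ± 0.0708 and 0.721 ± 0.0113 CPM per covered kilobase. Anchors covered 79.7 ± 2.94 kb of the chromosome 27 window in whole embryos and 57.2 ± 6.53 kb in neural folds, and CPM per covered kilobase were 2.33 ± 0.0564 and 0.874 ± 0.053 (SD, n = 3 each). The chromosome 2 window was covered over 84.2 ± 1.04 and 73.3 ± 5.58 kb, with 2.48 ± 0.18 and 1.20 ± 0.125 CPM per covered kilobase. The chromosome 3 window was covered over 85.2 ± 3.95 and 88.8 ± 0.52 kb, with 1.68 ± 0.188 and 2.90 ± 0.459. Without neural fold replicate 3 the count of windows was 908, and without neural fold replicate 2 or whole embryo replicates 1, 2 or 3 it was 2, 7, 5 and 2. The windows of chromosome 27 and chromosome 2 kept their calls in all 10 alternatives, which do not include other window sizes. Windows of 50 kb gave 0 higher and 3 lower by edgeR, with 2461 at an unadjusted 0.05, and windows of 250 kb gave 55 and 36. DESeq2 called 1031 windows.

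**Figure D2:**
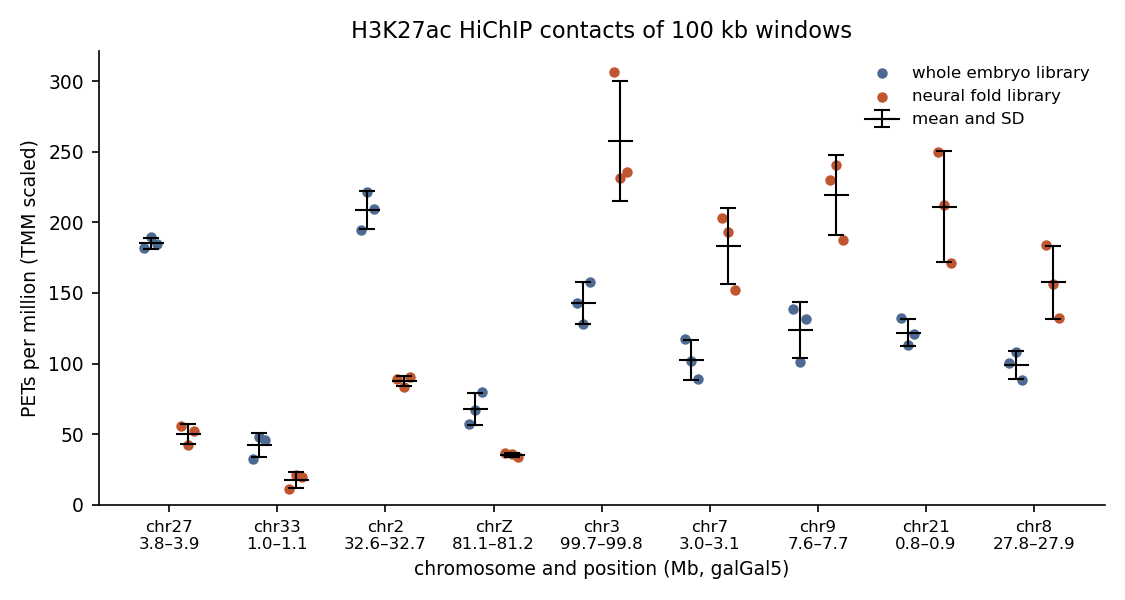
CPM (vertical axis, PETs scaled by TMM) in named 100 kb windows (horizontal axis, chromosome and position in Mb), with 1 point per library and bars for the mean and SD of 3 libraries. Whole embryos averaged 185 CPM at the chromosome 27 window, with 55.7, 42.2 and 52.1 in the neural fold libraries. The libraries of the groups do not overlap in any window drawn, which the rule for naming windows required.

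Summed over each merged anchor, PETs were lower in neural folds at 5 anchors and higher at 0 of 75633 tested with edgeR, where 7964 passed an unadjusted 0.05. DESeq2 called 2691 higher and 1394 lower. All 5 lie in the regions of chromosomes 27 and 2. The anchor from 3870262 to 3876547 on chromosome 27 held 21.2 ± 1.32 CPM in whole embryos and 4.70 ± 0.296 in neural folds (SD, n = 3 each; log2 fold change -2.18, adjusted p = 0.0201 from edgeR), and those from 3877374 to 3889065 and from 3805445 to 3815869 had log2 fold changes of -1.84 and -1.61. On chromosome 2, the anchors from 32638296 to 32671854 (71.2 ± 2.41 against 27.8 ± 2.05 CPM) and from 32683455 to 32707616 had log2 fold changes of -1.36 and -1.12. At the chromosome 27 anchor from 3870262 the libraries' own anchors covered 96.6% to 100% of the length in whole embryos and 50.6% to 63.2% in neural folds. At the chromosome 2 anchor from 32638296 they covered 95.4% to 100% and 81.9% to 95.4%. Without each library in turn edgeR called 0 anchors, with 5834 to 11470 at an unadjusted 0.05. Among anchors covered over at least 80% in every library, chosen after the data were examined, 463 were higher and 132 lower.

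Single loops were called mostly where an anchor was absent from the list of a library. Of 1318376 loops tested, 207 were higher and 419 lower in neural folds, and 467 of these 626 had an anchor that at least 1 library did not list, 74.6% against 5.32% of tested loops. The stretch of chromosome 27 between 3 and 4 Mb held 36 of them, all lower, and that of chromosome 2 between 32 and 33 Mb held 22, of which 20 were lower. The loops with the largest changes were listed at 0 in a whole group. On chromosome 10 the loop of 2625511 to 2628553 with 2630114 to 2678050 held 3.95 ± 0.878 CPM in neural folds and 0 in whole embryos, none of which listed both anchors. On chromosome 5 the loop of 26076188 to 26078024 with 26078025 to 26139352 held 4.52 ± 1.18 in whole embryos and 0 in neural folds (SD, n = 3 each). DESeq2 called 693 higher and 698 lower. With PETs scaled within distance classes 279 were higher and 420 lower, and pairs of 10 kb bins gave 0 calls by edgeR with 42671 at an unadjusted 0.05. Without neural fold replicate 3 the count was 1241, and without whole embryo replicates 2 and 3 it was 365 and 345.

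Among the 87420 loops whose anchors were covered over at least 80% in every library, a comparison added after the data were examined, 503 were higher and 187 lower in neural folds. Coverage still differed within that limit: the anchors of 346 of the 503 were covered more in neural folds and those of 150 of the 187 less. Chromosome 21 between 0 and 1 Mb held 31 of them, chromosome 9 between 7 and 8 Mb 16 and chromosome 8 between 17 and 18 Mb 12, all higher, and chromosome 10 between 15 and 16 Mb held 26, of which 25 were higher. Chromosome 2 between 32 and 33 Mb held 8 and chromosome 27 between 3 and 4 Mb 6, all lower. Small chromosomes were raised as a whole: over all 100 kb windows the median log2 fold change was 0.16 on chromosome 21 and 0.09 on chromosome 10. It was -0.07 on chromosome 1. The share of PETs on chromosome 21 was 0.985%, 0.888% and 0.828% in neural fold replicates 1, 2 and 3. In whole embryos it was 0.768% to 0.835%. Whether the higher loops exceed such shifts was not tested. CPM were scaled here to the covered loops alone, so they exceed those of the loops above at like PET counts. The chromosome 9 loop of 7525563 to 7530472 with 7662628 to 7670154 held 2.16 ± 0.466 CPM in whole embryos and 14.8 ± 2.62 in neural folds (SD, n = 3 each), a log2 fold change of 2.74 with an adjusted p of 2.2e-08 from edgeR. The neural fold libraries held 29, 43 and 38 PETs of that loop. The chromosome 27 loop of 3799249 to 3803844 with 3818939 to 3825223 held 11.7 ± 1.96 and 2.59 ± 1.11 (SD, n = 3 each), a log2 fold change of -2.12 with an adjusted p of 1.4e-05 from edgeR. Both loops kept their calls in all 9 alternatives, whereas most other covered loops under the same naming rule kept theirs in between 2 and 6 of 9. Loops that were higher spanned a median of 192 kb and loops that were lower 36.4 kb, against 240 kb for the loops tested. Without neural fold replicate 3 the count of 690 became 1124, without neural fold replicate 2 it became 242, and without whole embryo replicates 1, 2 and 3 it became 370, 225 and 219. DESeq2 called 295 loops, but gave no adjusted p for 81354 of the 87420.

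The share of PETs spanning over 100 kb was 51.0% ± 1.39 in whole embryos and 53.1% ± 1.05 in neural folds (SD, n = 3 each), a difference of 2.03 percentage points that did not pass a two-sided exact permutation test (p = 0.2), for which 0.1 is the smallest p that 3 against 3 libraries allow. Without whole embryo replicate 1 the difference was 1.35 points (permutation p = 0.3).

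Chromosome Z held 5.46% ± 0.115 of PETs in whole embryos and 4.76% ± 0.0815 in neural folds (SD, n = 3 each). Each neural fold library lay below each whole embryo library. The exact permutation p was 0.1, or 0.363 after adjustment over the 29 chromosomes compared, a comparison added after the data were examined. Chromosomes 5, 7, 8, 9, 10, 11 and 12 were the 7 whose shares lay higher in every neural fold library, where chance gives non-overlapping groups to 10% of chromosomes. Anchors covered 50.1 ± 0.681 Mb of chromosome Z in whole embryos and 47.5 ± 2.49 Mb in neural folds, with 1.09 ± 0.0205 and 1.00 ± 0.0397 CPM per covered kilobase.

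**Figure D3:**
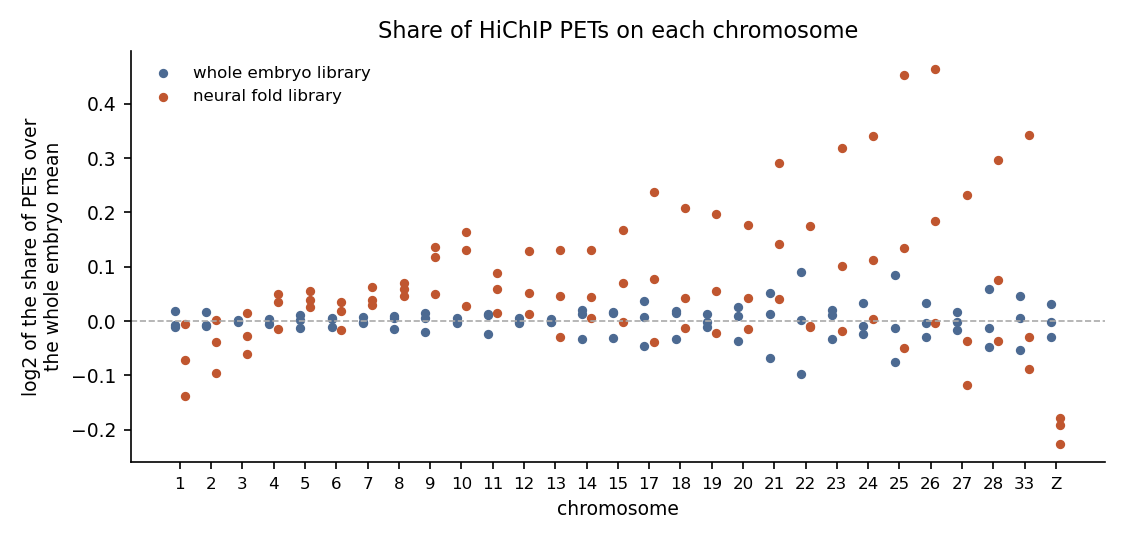
Log2 of each library's share of PETs on a chromosome over the mean share of the whole embryo libraries (vertical axis), for 29 chromosomes (horizontal axis), with 1 point per library. The neural fold libraries lie below the whole embryo libraries on chromosome Z, where the shares averaged 4.76% and 5.46%.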

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

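Covered loops, 100 kb windows, chromosome shares, 10 kb bins and the choice of covered anchors, with their alternatives, were tests chosen after the result was seen; the others were planned. The RNA count of 254 became 94 with a fold change of at least 2 (53 rising, 41 falling) and 129 at an adjusted p under 0.01, both stricter by construction, and stayed within 1.5 times in the other alternatives. The 4 called lists became 14 with the log2 fold change as statistic; the cause was not tested. They became 6 among genes with a mean count of at least 50 and 3 with a correlation of 0.05. Directions turned for neural plate and tube (adjusted p = 0.84) and paraxial mesoderm (0.67) among genes with a mean count of at least 50, and for retinoic acid genes (0.798) with the log2 fold change. None of these was called in the turned direction, but paraxial mesoderm was called up with the log2 fold change (0.0143). No paired analysis was possible because the RNA table gives no values per library, and the other planned RNA alternatives that need such values were not run, nor were those of contacts per gene, for lack of an annotation.

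DESeq2 gave 1391 loops, 295 covered loops, 4085 anchors and 1031 windows; the cause was not tested. It gave no adjusted p to 81354 of the covered loops and 153409 of the loops. At least 2 or 10 PETs gave 1280 or 413 loops; of the 626 calls, 609 were still tested with 10 PETs and 412 still called, and the cause was not tested. Bins of 10 kb gave 0 loops by edgeR, with 42671 at an unadjusted 0.05. Covered anchors gave 595 calls. Windows of 50 and 250 kb gave 3 (0 higher) and 91. Without each library in turn, loops ranged from 345 to 1241, covered loops from 219 to 1124, windows from 2 to 908, the share over 100 kb from 1.35 to 2.73 points, and anchors stayed at 0 (5834 to 11470 at an unadjusted 0.05). The highest counts came without neural fold replicate 3. Fewer samples enter those fits. Apart from the replicate block given next, the other alternatives kept counts within 1.5 times.

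Replicate numbers were checked for pairing. Deviations of same-numbered libraries correlated at 0.178, 0.143 and 0.0994 over windows, and those of other pairs at -0.115 to -0.00226. The numbers were not taken as pairs because the last of the 3 lay under the limit of 0.1, although each library correlated best with its own number. With a replicate block, loops numbered 23, covered loops 1132, anchors 0 (7537 at an unadjusted 0.05) and windows 121, and the share gave a permutation p of 0.25 within pairs, the smallest possible. The loop and anchor calls given above therefore depend on leaving the pairs out.

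Named loops kept direction and call in 117 of 120 alternatives, covered loops in 55 of 90, anchors in 21 of 56 and windows in 67 of 100, with none reversed. Every named loop was listed at 0 in a whole group, and its alternatives reuse the same merged anchors. They therefore do not check whether a missing anchor made the call. Pairs of 10 kb bins, which are not among these alternatives, gave 0 calls by edgeR. A simulated 2-fold change was recovered for 0 of 100 loops, 27 of 100 covered loops, 41 of 100 anchors and 99 of 100 windows.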

Other observations

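The permutation test over other cell types, the values per covered kilobase, the distance scaling of windows, the tests on chromosome Z and the check of neighbouring genes were chosen after the result was seen; the list tests and their alternatives were planned. Further gene groups in the authors' deposited table held 1 or 2 changed members without a called list. CYP26C1, which degrades retinoic acid, and RXRG, a retinoid receptor, fell with log2 fold changes of -1.11 and -0.99 in the authors' deposited table, while the retinoic acid list had an adjusted p of 0.856. LMX1B, a dorsal midbrain and hindbrain factor, fell by 0.72 on the log2 scale beside EN1, with an adjusted p of 0.312 for its list, and NOTO, a notochord factor, fell by 0.61 in the authors' deposited table. Notochord and floor plate genes had the other sign, with a median log2 fold change of 0.49 in the authors' deposited table and an adjusted p of 0.0848 (range over alternatives 0.0143 to 0.197). EGR1, an immediate early gene, rose by 1.74 and OASL, an interferon response gene, by 1.15 on the log2 scale in the authors' deposited table, with 0.939 for FGF targets and 0.0515 for innate response genes.

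List tests gave an adjusted p of 0.0515 for Wnt ligands and receptors (down) and for heart and endoderm genes (both up), and 0.0656 for forebrain (up) and BMP targets (down). Over their alternatives these ranged from 0.0287 to 0.197 for Wnt ligands and receptors, 0.00647 to 0.235 for endoderm, 0.015 to 0.32 for forebrain and 0.129 to 0.198 for BMP targets. Some lists share genes, so they are not separate evidence. DRAXIN, also listed as a crest specifier, was the only called member of the Wnt ligand and receptor list. MSX1 was in the specifier, border and BMP lists. Among genes with a mean count of at least 50 the heart list was called at 0.0137 (range over its alternatives 0.0128 to 0.18) and the innate response list at 0.0299 (0.015 to 0.18), both up. The remaining lists gave 0.34 for border genes, 0.312 for Notch targets and paraxial mesoderm, 0.202 for blood and endothelium and for cell cycle genes, 0.184 for apoptosis and 0.468 for hedgehog targets. Markers of blood and heart, cell types outside the folds, had medians above 0 in the authors' deposited table, 0.30 for blood and endothelium and 0.29 for heart, where ACTC1 rose. Random lists matched on mean count had medians of 0.08 and 0.07 in that order.

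The fall of crest genes beside the rise of surface ectoderm genes is 1 pattern. An upward drift of genes with low counts is argued against for the placode and epidermis list. Among genes with a mean count of at least 50 that list kept an adjusted p of 9.0e-06 in the list test. The range over its alternatives was 9.0e-06 to 0.00647. These values say nothing of the drift in lists of other cell types. Fewer crest cells in the injected folds could raise markers of every other cell type alike; over 130 genes of 8 other cell types a permutation test of differences between the lists gave p = 0.845, which does not show that they moved alike, and the medians ran from 0.01 for neural plate and tube to 0.55 for endoderm. A p53 response to the morpholinos may contribute, with an adjusted p of 0.0117 for its list that ranged from 0.0116 to 0.0811 over alternatives. Both stay open and cannot be told apart from the knockdown itself, which was not tested separately, because the knockdown folds differ from the control folds in the morpholinos they received and no further control was used here.

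Lower PET counts of neural folds at the chromosome 27 and chromosome 2 windows are another pattern. A smaller part of each window was called as anchors in neural folds, with log2 ratios of covered length of -0.48 on chromosome 27 and -0.20 on chromosome 2. Per covered kilobase the log2 ratios were still -1.41 and -1.04, so a smaller covered length is argued against as the whole cause. Every neural fold library also lay below every whole embryo library per covered kilobase. The rule for naming windows required this of CPM, so that separation was likely beforehand and is no further support. A genome-wide shift of contact distance is also argued against, since PETs scaled within distance classes gave -1.87 and -1.24. The class shares differed little between libraries, so this scaling could move the values only slightly. A change of contact distance local to these windows was not tested. Tissue may account for the pattern, as a hypothesis found on the same data. It was not tested apart from the stage tags of the characteristics or from the amount of acetylation pulled down.

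The smaller share of chromosome Z in neural folds is a further pattern. A tilt between large and small chromosomes is argued against, since the median log2 fold change of Z windows lay 0.14 below that of chromosome 1 windows (a difference of -0.14), and Z PETs per 100 PETs of chromosome 1 were 29.9 ± 0.344 in whole embryos and 27.4 ± 0.811 in neural folds (SD, n = 3 each). Fewer bases called as anchors on Z are argued against as the whole cause, since PETs per covered kilobase had a log2 ratio of -0.12. Female birds carry a single Z and a W, so pools with more females could lower Z: 86.6% of 767 Z windows lay below 0. W contacts in CPM were 52.5 ± 15.6 and 50.5 ± 42.7 (SD, n = 3 each) and overlap between groups. Neural fold replicate 3 had 99.5, while neural fold replicates 1 and 2 had 31.2 and 20.9, below each whole embryo library (68.7, 37.6 and 51.2), the opposite of what more females would give. The sex of the pooled embryos is not in the labels, so this stays open, as does tissue, which was not tested.

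Other groupings of the 6 HiChIP libraries into 3 and 3 make 10 splits with the real one, too few for a share under 0.05. The real split gave 626 loops, 690 covered loops, 5 anchors and 57 windows, and the highest of the other splits 468, 2, 0 and 1, so for each of these results only 1 split, the real one, reached its count. A check of whether changed genes lie next to each other is void, since the reference table matched 195 of the 254 changed genes, 76.8%, under the 80% needed.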
